A study of Bos taurus with 44 samples.

How the data were processed

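Gene expression was measured in mononuclear cells, mainly lymphocytes and monocytes, that were isolated from the blood of Holstein cows on a density gradient 6 days after immunization. Per the labels, cows were classed as high or low for an antibody response (Ab) or for a cell-mediated response (DTH in the labels). The 44 arrays were taken to come from 11 cows. The labels name 1 cow for both traits and give no animal identities, so other cows of the same number in different groups were taken as different animals, which the comparison of all cows and the difference between traits rest on. That 1 cow was high for both traits and is called the shared cow, 2 further cows were high-Ab, 2 further cows were high-DTH, 3 were low-Ab and 3 were low-DTH. Each cow had 4 arrays, except high-DTH cow 2 with 5 and low-DTH cow 3 with 3.

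Per the labels' protocols, total RNA went through 1 round of amplification, and the amplified RNA of a cow and of a common RNA standard, also from blood mononuclear cells, were labelled with Alexa647 and Alexa555 and hybridised together to a spotted cDNA array. The dyes were swapped on part of the arrays of each cow. The values deposited by the authors are 1 log ratio per spot and array, read here as log2. The log base, the scanner, the background correction and the normalization are not given in the sources used here. Array medians lay between −0.08 and 0.07 and array means between −0.02 and 0.02, so the values had been centred. No spot intensities were analysed here, so the signal over background of a spot is unknown, and only the number of arrays and cows limits the precision that can be stated.

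The direction of the ratios is not stated either. Arrays of the same cow with opposite dyes correlated above 0 on average (mean r = 0.37 over 44 pairs), so swapped arrays were taken as already turned and no sign was applied. That the ratios run cow over standard is likely, since that is the usual convention for a deposited ratio against a common reference, but no label says so. Higher and lower below describe the deposited ratio, and all directions would swap together under the opposite convention.

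For 3 arrays the direction is not settled. Arrays 1 and 2 of low-Ab cow 1 and array 3 of low-DTH cow 3 correlated below 0 with other arrays of the same cow, down to r = −0.73 and r = −0.58. Their mean r with arrays of other cows lay between −0.23 and −0.20, whereas it was at least 0.05 for each of the other 41 arrays. The 3 arrays were kept as deposited in the main values, and each comparison is also given with their signs turned. Among the other 41 arrays, 3 pairs from different cows had r under −0.3, the lowest at −0.34. Within a cow, r was below 0 between arrays 2 and 3 (−0.24) and between arrays 2 and 4 (−0.02) of high-DTH cow 3.

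The table held 1680 spots. The platform annotation gave 1 gene symbol for 1224 spots, several symbols for 16 and none for 440. The named spots covered 142 symbols, of which vapA, a bacterial gene with 16 spots, was set aside as a control. Of the other 141 genes, 131 had 8 spots and 10 had 16. Entrez identifiers of 137 genes matched the bovine reference table with the same symbol, and the array's name was kept for the other 4. Spots of a gene were averaged, and spots without a single symbol were tested 1 by 1 and not named. The 2 clones of CCL2 disagreed in the Ab comparison (0.12 and −0.12), while those of CCL8 and CSF1 had the same sign in both comparisons.

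Arrays of a cow are technical replicates. They were averaged within each dye orientation, then over the 2 orientations, which gave 1 value per cow. A feature needed a value in each orientation of each cow. Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were 3 high-Ab against 3 low-Ab cows and 3 high-DTH against 3 low-DTH cows, each with the shared cow in the high group, the difference between the 2 high-minus-low effects in 1 fit of all 11 cows, and all 5 high against all 6 low cows. The shared cow cancels out of the difference between the 2 effects, which leaves 2 high and 3 low cows per trait. Leaving this cow out still changes the weight of the other high cows. A two-sided exact permutation test of 3 against 3 cows cannot go below p = 0.1. Cows are the replicates behind the limma p-values of single features and the exact permutation p-values. The array-level alternative instead draws its p-values from arrays with a fitted correlation within a cow. The camera test of gene lists, described next, compares the genes of a list with other genes. At its small preset correlation between genes, genes taken as nearly independent act as the replicates more than cows do.

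Of 25 gene lists, 17 had at least 3 measured genes and were tested with limma's camera at an inter-gene correlation of 0.01 against the other named genes, with adjustment over the 17 lists. Each was also tested with an estimated correlation and with fry. Gene lists, comparisons, most alternatives and the rule for named genes were fixed before the data were examined. That rule took, in the Ab and the DTH comparison, up to 20 genes past the adjusted threshold, filled up with the genes of smallest p whose high and low cows did not overlap, plus the 2 genes of smallest p from each list as examples. For the other comparisons it took the 5 genes of smallest p. Other genes in the text are members of a list or cell type markers.

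Alternatives covered centring, quantile normalization, each dye alone, plain mean or median over arrays, spots tested 1 by 1, noisy genes left out, fewer required values, robust eBayes, an array-level fit with the cow as a random block, the shared cow left out and each cow left out in turn. Added after the data were seen were the 3 arrays turned or left out, arrays 1 and 2 or arrays 3 to 5 alone, named genes alone, unnamed spots in the background of camera, camera on ranks, the shared cow left out together with an estimated correlation, and the trait as a covariate. Arrays 1 and 2 and arrays 3 to 5 were looked at apart because, among the high-DTH and low-DTH cows, arrays of different cows correlated more within a set (mean r = 0.37 and 0.28) than across sets (0.12). These values leave out the shared cow and the 3 arrays of unsettled sign. Among the other cows, the shared cow included, mean r was 0.22 within and 0.23 across sets, also without the 3 arrays. In arrays 1 and 2, low-Ab cow 1 had only arrays of unsettled sign. In arrays 3 to 5, low-DTH cow 3 had only its array 3, also of unsettled sign.

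The tests were checked on simulated data with the spread of the real cows and no correlation between genes. In 20 simulated sets of 561 features, a planted log2 difference of 1 was recovered in 78.8% of cases in the Ab comparison, 83.8% in the DTH comparison, 70.8% in the difference between traits and 94% with all cows. For a planted difference of 0.5 the shares were 42%, 45%, 33.5% and 69.5%. Each set held 20 planted features at each of the sizes 0.5, 1 and 2, and recovery may differ with fewer changed features. A shift of 0.3 planted in the T cell list was found by camera in 20 of 20 sets of 141 genes in the Ab comparison at the preset correlation and in 2 with an estimated one. In the DTH comparison these counts were 20 and 3. At the preset correlation another list, with no shift planted, was called in 2 of the 20 Ab sets and 1 of the 20 DTH sets, and with nothing planted in 2 and 0, against 0 in each case with an estimated correlation. Since the simulated genes were independent, these counts cannot show which setting holds where the members of a list correlate.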

Results

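Expression of 141 named immune and endocrine genes was compared in blood mononuclear cells of Holstein cows with high or low immune responses, 6 days after immunization. The 44 two-colour arrays covered 11 cows, taking cows of different label groups as different animals, in 4 groups of 3 for high and low antibody response (Ab) and high and low cell-mediated response (DTH), with 1 cow counted in both high groups. Each array held RNA of 1 cow and a common RNA standard, and values are deposited log2 ratios averaged to 1 value per cow. The median SD was 0.13 between spots of a gene on an array, 0.18 between arrays of a cow and 0.10 to 0.13 between cows of a group. The last is an SD of means over arrays, so it includes spread between arrays, which was not separated from that between cows. Control spots of the bacterial gene vapA had a mean ratio of 0.03 ± 0.09 (SD, n = 11 cows).

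The direction of the ratios is not stated and is read here as cow over standard. Of the 44 arrays, 3 ran against the rest, and the sign of these 3 is not settled. They belonged to low-Ab cow 1, where the r between arrays 2 and 3 was −0.73, and to low-DTH cow 3, where the r between arrays 1 and 3 was −0.58. The counts, the called lists and some of the main genes of each comparison are therefore also given with the 3 odd arrays turned, while other values are as deposited unless stated. As deposited, the values of these 2 cows average arrays that ran against each other, so that a gene can cancel towards 0. Low-Ab cow 1 is 1 of only 3 low-Ab cows behind each main Ab value. Some other arrays, kept as deposited throughout, also agreed poorly. In high-DTH cow 3, r was −0.24 between arrays 2 and 3 and −0.02 between arrays 2 and 4. Arrays 3 and 4 of low-DTH cow 2 had r below 0 with 19 and 15 of the 40 arrays of other cows.

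**Figure D1:**
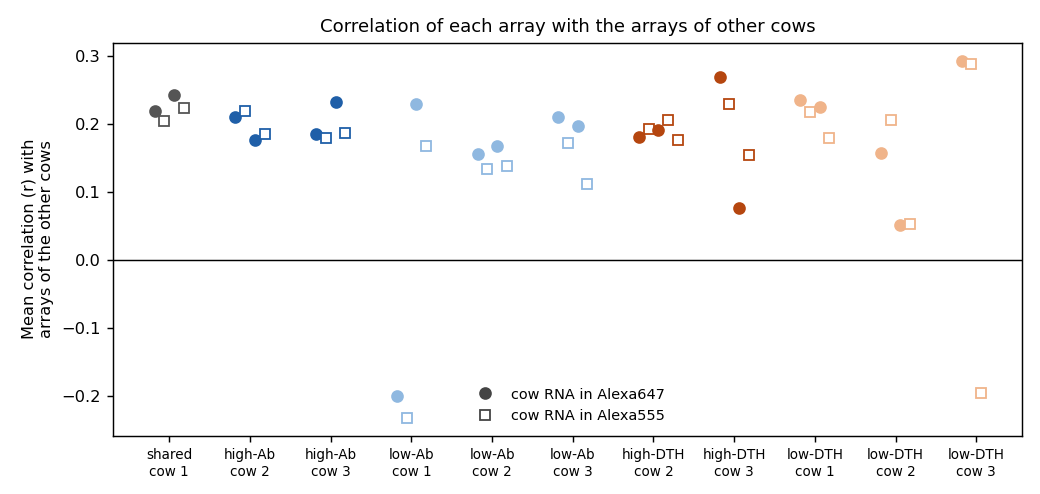
Mean correlation r of each of the 44 arrays (y axis) with the arrays of all other cows, by cow (x axis), with filled circles for cow RNA in Alexa647 and open squares for cow RNA in Alexa555. Arrays 1 and 2 of low-Ab cow 1 and array 3 of low-DTH cow 3 lie between −0.23 and −0.20, and the other 41 arrays lie above 0.

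The first comparison set cows of high antibody response against cows of low antibody response. The 2 named genes of smallest p were CD247, a signalling chain of the T cell receptor complex, with higher ratios in high-Ab cows, and IL1B, which encodes the inflammatory cytokine interleukin 1 beta, with lower ratios. CD247, the CD3 zeta chain, was at 0.65 ± 0.15 in high-Ab and 0.06 ± 0.09 in low-Ab cows (mean ± SD, n = 3 each), a difference of 0.59 ± 0.11 (SE). CD3D differed by 0.62 ± 0.21 and CD3G by 0.53 ± 0.18. IL1B was at −0.87 ± 0.39 in high-Ab and 0.05 ± 0.10 in low-Ab cows, a difference of −0.91 ± 0.20. None of these passed adjustment, and limma called 0 of 562 features, with a smallest adjusted p of 0.217. Without the shared cow 1 feature passed, IL1B (−1.13, adjusted p = 0.0432). In low-Ab cow 1, CD247, CD3D and CD3G were at −0.03, −0.08 and −0.11 as deposited. With the odd arrays of this cow turned they were at 0.39, 0.35 and 0.19, whereas IL1B was at −0.04 either way. The differences of these CD3 chains as deposited thus rest partly on a cow whose arrays ran against each other.

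Of the 141 genes, 15 had no overlap between the high-Ab and low-Ab cows, against 14.1 that chance gives (10% for 3 against 3), with 7 higher and 8 lower. Besides the CD3 chains, those with higher ratios included the cytokine IL18 (0.31 ± 0.12), the T cell coreceptor CD4 (0.19 ± 0.10), the interleukin 12 receptor chain IL12RB2 (0.17 ± 0.08) and LOC617313 (0.22 ± 0.10). Those with lower ratios included BOLA-DQA2 of MHC class II (−0.71 ± 0.23), the Fc receptor gamma chain FCER1G (−0.40 ± 0.14), the interleukin 1 receptor antagonist IL1RN (−0.47 ± 0.19) and the prolactin receptor PRLR (−0.14 ± 0.08). ADAM17 (−0.11 ± 0.09), CSF2RB (−0.07 ± 0.08) and PRP6 (−0.19 ± 0.10, but 0.05 over arrays 1 and 2 alone) completed the set. At an unadjusted p under 0.05 there were 37 features, against 28.1 by chance, 10 of them named genes. With the 3 arrays turned, 0 features passed and 54 had an unadjusted p under 0.05, all 15 genes kept their sign and 14 stayed without overlap (not IL1RN), and CD247 stood at 0.45 ± 0.13 and IL1B at −0.91.

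Among the 17 lists, camera called T cell genes, with higher ratios in high-Ab cows. Of 10 measured members 7 were higher and 3 lower, with a median difference of 0.19 and a camera adjusted p of 0.00137, but the list was not called with an estimated correlation (adjusted p = 0.624). The members furthest from 0 were the CD3 chains, CD247, CD3D, CD3G and CD3E (0.41 ± 0.21), whereas CD28 (−0.04 ± 0.10), the homing receptor CCR7 (−0.02 ± 0.14) and the activation marker CD69 (−0.09 ± 0.53) were near 0. Adjusted over the list alone 1 member passed, CD247 (0.0106), and over all features 0 did. The list was also not called by fry (adjusted p = 0.612), with the 3 arrays turned (adjusted p = 0.0850), without the shared cow (0.0593) or without low-Ab cow 1 (0.0779). Chemokine and chemokine receptor genes were lower in 13 of 14 cases, among them CXCL8 (−0.70 ± 0.44) and CCL3 (−0.56 ± 0.35), with an adjusted p of 0.301, and of 0.0275 without the shared cow. Without that cow Th1 and cytotoxic genes had 0.0368, and with an estimated correlation both lists then had an adjusted p of 0.776. MHC class I genes were higher in 6 of 7 cases (adjusted p = 0.351) and interferon response genes in 5 of 5 (0.301). The adjusted p with these arrays turned was 0.0822 for chemokine genes and 0.0850 for MHC class I and for interferon response genes. Of the 4 B cell genes 1 was higher and 3 were lower (adjusted p = 0.496), and the direction of this list changed with the 3 arrays turned (adjusted p = 0.950).

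The second comparison set cows of high cell-mediated response against cows of low cell-mediated response. The 8 named genes of smallest p were CD3D and CD3G of the T cell receptor complex, the chemokine receptors CXCR4, CCR4 and CCR3, the chemokine CCL3 and the cytokine genes IL1A and IL1B, with higher ratios in the 3 high-DTH cows. CD3D was at 1.03 ± 0.17 in high-DTH and 0.35 ± 0.07 in low-DTH cows (mean ± SD, n = 3 each), a difference of 0.68 ± 0.11 (SE), and CD3G differed by 0.56 ± 0.16. The chemokine receptors CXCR4, CCR4 and CCR3 differed by 0.58 ± 0.12, 0.38 ± 0.11 and 0.65 ± 0.20. IL1A was at −0.01 ± 0.47 in high-DTH and −1.03 ± 0.04 in low-DTH cows, a difference of 1.02 ± 0.23, and CCL3 and IL1B differed by 1.05 ± 0.32 and 0.72 ± 0.22. No gene passed adjustment here either, with 0 of 565 features called by limma and a smallest adjusted p of 0.488.

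In all, 22 of the 141 genes had no overlap between high-DTH and low-DTH cows, against 14.1 by chance, with 12 higher and 10 lower. Among the 20 of smallest p, the others with higher ratios were B2M, the light chain of MHC class I (0.38 ± 0.13), CD3E (0.35 ± 0.16), the bacterial lipopolysaccharide receptor TLR4 (0.15 ± 0.09) and CCR1 (0.11 ± 0.08). Those with lower ratios were the immunoproteasome subunits PSMB10 (−0.36 ± 0.13) and PSMB9 (−0.38 ± 0.15), the chaperone CALR (−0.26 ± 0.10), the B cell genes CD40 (−0.30 ± 0.12) and CD72 (−0.13 ± 0.09), the growth factor binding protein IGFBP2 (−0.20 ± 0.09), LTB (−0.22 ± 0.11) and TXLNA (−0.13 ± 0.08). At an unadjusted p under 0.05 there were 55 features, against 28.2 by chance, 12 of them named genes. With the 3 arrays turned, 0 features passed, 69 had an unadjusted p under 0.05 and all 22 genes kept their sign, although CXCR4 moved to 0.36 and CD3E to 0.20, and 18 stayed without overlap (not B2M, CXCR4, CD3E and CD3G). Of genes looked at by array set after their values had been seen, several differed between the sets, which was not tested. In arrays 3 to 5, low-DTH cow 3 was represented by array 3 alone, whose sign is not settled. For these genes a difference between the sets therefore cannot be told apart from that array. The sets also differed without it and without the shared cow. Over all spots, arrays of different DTH cows then had a mean r of 0.12 across sets, against 0.37 and 0.28 within a set. Over arrays 3 to 5 alone the differences were −0.21 for IL1B, 0.17 for IL1A, −0.18 for CCL3, 0.06 for LTB and −0.06 for CCR1, against 1.02, 1.28 and 1.49 for IL1B, IL1A and CCL3 over arrays 1 and 2, whereas CD3D stood at 0.52 over arrays 1 and 2 and at 1.09 over arrays 3 to 5.

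In the DTH comparison camera called 2 of the 17 lists, but 0 with an estimated correlation (adjusted p = 0.589 for chemokine and 0.593 for T cell genes, and 0.570 for each with the 3 arrays turned). Chemokine and chemokine receptor genes were higher in 10 of 14 cases (median 0.11, camera adjusted p = 0.00186, 0.00632 with the 3 arrays turned), led by CXCR4, CCR4, CCR3 and CCL3. T cell genes were higher in 9 of 10 cases (median 0.21, camera adjusted p = 0.00406, 0.0356 with the 3 arrays turned and 0.0518 with them left out, where the call was lost), with CD27 (−0.10 ± 0.10) the exception. Adjusted over the list alone, CXCR4 (0.0339) passed among chemokine genes and CD3D (0.00592) among T cell genes. The fry test gave an adjusted p of 0.152 for chemokine and 0.348 for T cell genes. Over arrays 3 to 5 alone the chemokine list had an adjusted p of 0.301, and without low-DTH cow 2 the T cell list had 0.0861.

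MHC class I genes, which process and present peptides, had lower ratios in high-DTH cows in 6 of 7 cases, with B2M the exception (adjusted p = 0.0727, and 0.00632 with the 3 arrays turned). The 4 B cell genes CD40, CD72, IGHM (−0.68 ± 0.58) and JCHAIN (−0.26 ± 0.16) were all lower (adjusted p = 0.0727, and 0.0589 turned). With an estimated correlation the adjusted p was 0.593 for either list, and 0.570 for MHC class I genes with the 3 arrays turned. Interferon response genes were lower in 5 of 5 cases (adjusted p = 0.314) and endocrine and growth factor genes in 9 of 10 (0.348).

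IL1B and IL1A had lower ratios in high-Ab and higher ratios in high-DTH than in the low cows, and while neither passed within a trait, the difference between the 2 effects passed its test. In the fit of all 11 cows, the high-minus-low effect of IL1B was lower for Ab than for DTH by −1.63 ± 0.25 (limma adjusted p = 0.0393) and that of IL1A by −1.44 ± 0.26 (adjusted p = 0.0421). The shared cow cancels out of this difference, so its high side rests on 2 further cows per trait. The mean IL1B ratio was 0.05 in low-Ab and −1.28 in low-DTH cows, against −0.87 and −0.56 in the high groups of these traits. The chemokine CCL3 (−1.61 ± 0.43, adjusted p = 0.142), CXCR4 (−1.0 ± 0.34, adjusted p = 0.294) and PSMB9 (0.65 ± 0.22, adjusted p = 0.294) came next and did not pass. In all, 7 of 561 features passed, the other 5 being unnamed spots. With the 3 arrays turned 0 features passed, although the IL1B and IL1A differences were larger (−1.81 ± 0.38 and −1.66 ± 0.33, adjusted p = 0.0592 for each). Over arrays 3 to 5 alone they were −0.73 and −0.57 (adjusted p = 0.991), with low-DTH cow 3 represented only by its array of unsettled sign. The count was also 0 with quantile normalization, with either dye alone, over arrays 1 and 2 alone, and without the shared cow, high-Ab cow 2, high-Ab cow 3 or any 1 of the 6 low cows.

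**Figure D2:**
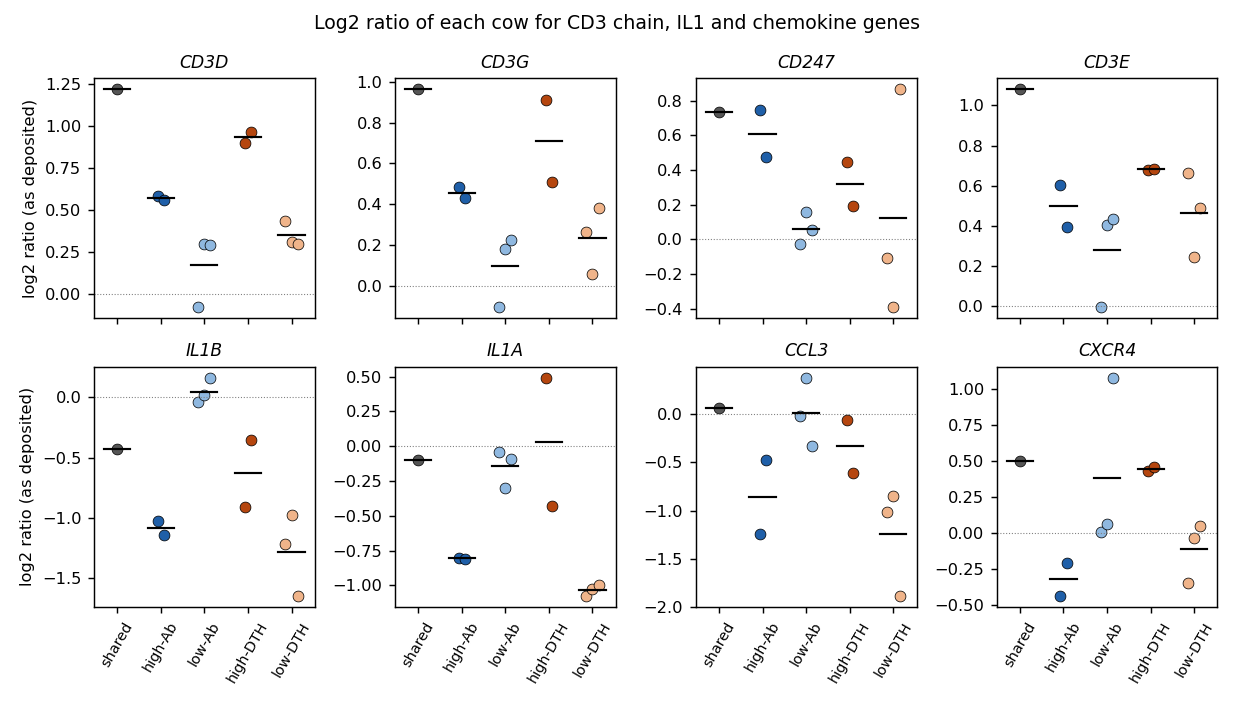
Log2 ratio as deposited (y axis) of each of the 11 cows for 4 CD3 chain genes and 4 inflammatory or chemokine-related genes, by group (x axis), with a point per cow and a bar at the group mean. IL1B lies near 0 in low-Ab cows (mean 0.05) and below 0 in low-DTH cows (mean −1.28), while CD3D as deposited lies higher in every high cow than in every low cow.

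Across the 141 genes, the high-minus-low differences of the 2 traits had r = −0.07, with the same sign in 53.2% of genes. Their rank correlation was 0.06, so the sign of the relation depended on the measure. Genes are not independent replicates, and the shared cow alone gave r = 0.16 ± 0.16 (SD over 1000 simulations) in cows without any difference. The covariance was −0.00401, against 0.00696 in the simulations. Without the shared cow r was −0.43, and with the 3 arrays turned it was −0.29, both without a simulated spread of their own. CD3D, CD3G and CD247 lay on the side of higher ratios in both traits, and IL1B, IL1A, CCL3 and CXCR4 on opposite sides.

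**Figure D3:**
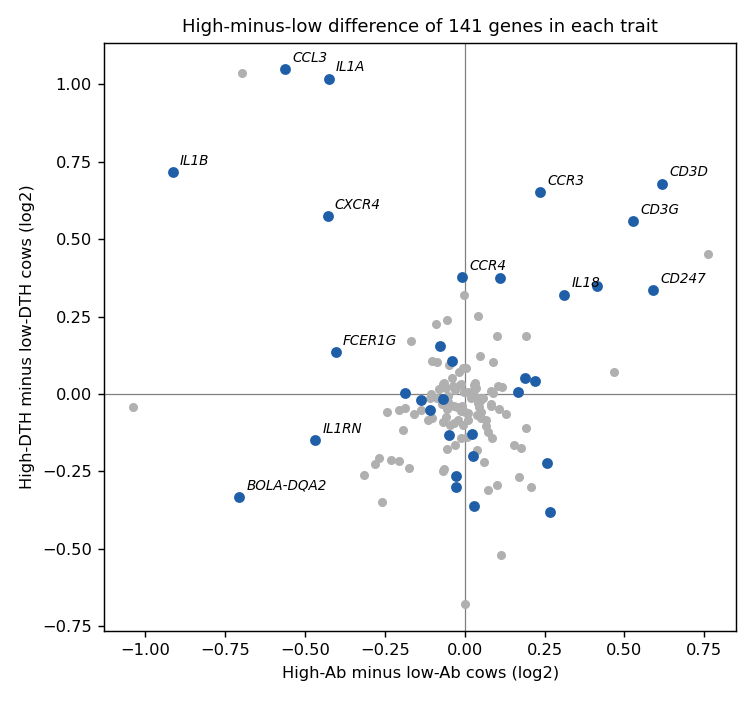
Difference between high and low cows in log2 ratio of 141 genes in the Ab (x axis) and the DTH comparison (y axis), with a point per gene, genes that the naming rule took in either comparison in blue and all others in grey. CD3D lies at 0.62 and 0.68, and IL1B at −0.91 and 0.72.

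With each cow used once, CD3 chain genes again had higher ratios in the 5 high than in the 6 low cows. CD3D was at 0.85 ± 0.28 against 0.26 ± 0.17 (mean ± SD), a difference of 0.59 ± 0.13, and CD3G differed by 0.49 ± 0.12, without overlap between high and low cows for either gene. IL18 differed by 0.28 ± 0.09, CD3E by 0.32 ± 0.14 and JCHAIN, the joining chain of polymeric immunoglobulin, by −0.25 ± 0.11. No feature passed (0 of 561 by limma, smallest adjusted p = 0.335), and 20 had an unadjusted p under 0.05, against 28.1 by chance. With the 3 arrays turned these counts were 0 and 23, CD3D and CD3G differed by 0.44 and 0.40, and both overlapped, with low-DTH cow 3 at 0.77 and 0.63 and the lowest high cow at 0.56 and 0.43.

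Over all cows 1 list was called, T cell genes, with 8 of 10 higher and a camera adjusted p of 3.03e-05 (0.0247 with the 3 arrays turned, and adjusted p = 0.463 with an estimated correlation, 0.837 turned). The mean of the 10 genes was 0.42 ± 0.12 in the 5 high and 0.21 ± 0.17 in the 6 low cows, a difference of 0.21 ± 0.09 with a two-sided exact permutation p of 0.0498, or 0.846 after adjustment over the 17 lists. With the 3 arrays turned that difference was 0.12 ± 0.09 (exact permutation p = 0.208). The 4 B cell genes were all lower (camera adjusted p = 0.195), and the 9 monocyte genes, with 4 higher and 5 lower, had a mean difference of 0.00 ± 0.03.

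Markers of other blood cells were examined beside these lists, and none passed adjustment. The monocyte marker CD14 differed by −0.05 ± 0.10 in the Ab and 0.09 ± 0.19 in the DTH comparison, and the monocyte list by medians of −0.05 and 0.02 (camera adjusted p = 0.582 and 0.500). The neutrophil granule gene LTF differed by −1.04 ± 0.54 in the Ab and −0.04 ± 0.22 in the DTH comparison, while CXCR2 differed by −0.02 ± 0.10 and 0.03 ± 0.10. CD163L1, a marker of bovine gamma delta T cells, differed by 0.76 ± 0.35 and 0.45 ± 0.37. The natural killer cell genes FCGR3A and XCL1 differed by −0.23 ± 0.55 and −0.16 ± 0.15 in the Ab and by −0.21 ± 0.31 and −0.06 ± 0.09 in the DTH comparison. The stress gene SOD1 differed by 0.47 ± 0.18 and 0.07 ± 0.33. Housekeeping genes had median differences of 0.10 and −0.06 (camera adjusted p = 0.301 and 0.744).

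The remaining lists were not called in either trait. Th1 and cytotoxic genes had medians of 0.07 and −0.03 (adjusted p = 0.213 and 0.874) and Th2 and regulatory genes of −0.03 and 0.02 (0.978 and 0.487). IFNG (0.11 ± 0.12 and −0.05 ± 0.13) and IL4 (−0.05 ± 0.11 and −0.02 ± 0.08) lay near 0. Members further from 0 included IL18 (0.31 and 0.32) and, in the DTH comparison, IL15 (−0.31), CCR3 (0.65) and CCR4 (0.38). Interleukins and their receptors had medians of −0.02 and 0.01 (0.703 and 0.282), and MHC class II genes of −0.21 and −0.33 (0.351 and 0.348). Toll-like receptor genes had −0.06 and 0.09 (0.496 and 0.282), complement and Fc receptor genes −0.23 and −0.21 (0.496 and 0.282), and TNF family genes 0.03 and −0.06 (0.582 and 0.348). Apoptosis genes had 0.05 and −0.16 (0.619 and 0.512), adhesion genes 0.04 and −0.06 (0.942 and 0.512), and endocrine genes −0.01 in the Ab comparison (0.591). The median differed in sign from the mean for Th2 genes in the Ab comparison, and from the direction of the test for adhesion genes in the Ab and housekeeping genes in the DTH comparison.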

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

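Tests of the 3 odd arrays, of the array sets, of the T cell share and of the monocyte share were chosen after the results they concern had been seen, and the other tests before. For the T cell genes, the values with the 3 arrays turned and the adjustment over lists were also added to the weighing afterwards, as was the requirement on the spread of the monocyte genes.

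The IL1B and IL1A effects differed between the traits by −1.63 and −1.44, and 5 unnamed spots at 2 positions of the repeated layout differed by −0.93, −0.76, −0.88, −0.91 and −1.0 (adjusted p from 0.0393 to 0.0427 in limma). The shared cow cancels out of this difference, which leaves 2 high and 3 low cows per trait. In 44 groups tested for a cow far from the others, where chance singles out about 5%, 2 such cows were found. CD3D in low-Ab cow 1 was at −0.078, the nearest low cow being at 0.29, and this cow stood at 0.35 with its arrays 1 and 2 turned. The mean of the endocrine genes in low-DTH cow 2 was −0.072, the nearest low cow being at 0.0026.

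The first pattern weighed was that of the 3 odd arrays, which had a mean r of −0.515 with the other arrays of their cows. A noisy hybridization would bring r near 0, which this value argues against, although the arrays were singled out by this same r. RNA of another cow, with the sign of the other arrays, would correlate above 0 with arrays of other cows. The highest mean r of the 3 arrays there was −0.196, which argues against it. RNA of another cow with an unturned sign would also give r below 0 and stays open. Signs left unturned stay open, since turning only changes the sign of the r that singled out these arrays (0.515, against a lower quartile of 0.273 in the 60 other pairs of arrays of 1 cow) and cannot support them. By the labels, low-Ab cow 1 was in Alexa647 on its array 1 and in Alexa555 on its array 2. Leaving only swapped arrays unturned would thus reverse 1 of these 2 arrays, not both. In this cow r was −0.73 and −0.67 for the pairs of opposite dyes 2 with 3 and 1 with 4. It was −0.28 for the same-dye pairs 1 with 3 and 2 with 4, and the reason was not tested. Per the labels, arrays of a cow held RNA of the same cow, and no biological explanation was tested.

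The second pattern was that of T cell genes higher in high cows. Of 462 splits of the 11 cows, 23 gave as large a difference in the mean T cell score (real 0.21, highest other −0.26, exact permutation p = 0.0498), but the list was 1 of 17 (adjusted p = 0.846) and the difference was 0.12 ± 0.09 with the 3 arrays turned (exact permutation p = 0.208), so chance is not excluded. Without the 2 low cows that hold these arrays the difference was 0.19 ± 0.09 (exact permutation p = 0.0317, not adjusted over the lists). These cows had the lowest and the highest T cell score of the low cows (−0.03 and 0.40), so leaving out both cannot decide their part. Without the shared cow the difference was 0.16 ± 0.09 (exact permutation p = 0.129), so the part of the shared cow stays open. A larger share of T cells could raise all T cell genes, but CD4, CD5, CD27 and CD28 differed by 0.055 ± 0.050 on average and the CD3 chains by 0.46 ± 0.12. This was first read as excluding a larger share. After that result had been seen, the 4 genes were also required to vary at least 0.5 times as much over arrays as the CD3 chains. The ratio was 0.469, so a compressed signal of the 4 genes keeps the share open, as it does higher CD3 expression per cell. Over all cows neither the gamma delta T cell marker CD163L1 (0.49 ± 0.27) nor the stress gene SOD1 (0.25 ± 0.21) lay over 2 SE from 0. In the Ab comparison both lay over 2 SE above 0 without passing adjustment, so these genes do not decide it.

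The third pattern was that of IL1B and IL1A in opposite directions in the 2 traits. Of 60 relabellings of the trait within the high and the low cows, 1, the real one, gave as many features as deposited (7, highest other 6). The margin was 1 feature, and 5 of the 7 were unnamed spots at 2 positions of the repeated layout, tested 1 by 1. Chance is therefore not excluded. The real count was 6 with each array centred on its median, 1 with a median over arrays, and 0 in limma with quantile normalization, either dye alone or the 3 arrays turned (54, 68, 23 and 86 at an unadjusted p under 0.05). The 9 monocyte genes differed by −0.066 ± 0.058 between the traits and the 2 IL1 genes by −1.54 ± 0.13, but the monocyte genes varied only 0.353 times as much over arrays, under the 0.5 also required of the T cell genes, so a different share of monocytes stays open. The IL1 difference was −1.82 ± 0.39 in arrays 1 and 2 and −0.65 ± 0.84 in arrays 3 to 5. Over all arrays with the 3 odd arrays turned it was −1.73 ± 0.33. In arrays 3 to 5 low-DTH cow 3 had only its odd array, and in arrays 1 and 2 low-Ab cow 1 had only its odd arrays. A difference of the IL1 genes between array sets therefore cannot be told apart from these arrays, or from the trait with this spread. A difference between the immune traits themselves stays open too, as a hypothesis.

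Other splits of the cows were also counted. Between high-Ab and low-Ab cows, 3 of 10 splits gave as many features at an unadjusted p under 0.05 (real 37, highest other 52) and 6 of 10 as many lists (real 1, highest other 2). Between high-DTH and low-DTH cows these were 2 of 10 (real 55, highest other 115) and 3 of 10 (real 2, highest other 4). For both, 10 splits are too few for a share under 0.05. Between all high and all low cows, 48 of 100 splits gave as many features (real 20, highest other 106) and 56 of 100 as many lists (real 1, highest other 4), so chance is not excluded. The split with 115 set the shared cow, high-DTH cow 2 and low-DTH cow 3 against the rest, with 10 features past the adjusted threshold against 0 in the real split, and what sets these cows apart was not tested. The split with 106 set the shared cow and 4 of the 5 DTH cows against the Ab cows and low-DTH cow 3, so it largely followed the trait for which cows were chosen; with the trait as a covariate and without the shared cow, limma called 0 features for high against low, with 14 at an unadjusted p under 0.05.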

How the results depend on the processing

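Turning or leaving out the 3 arrays, the array sets, named genes alone, unnamed spots in the background of camera, camera on ranks, the shared cow left out with an estimated correlation and the trait as a covariate were tried after the data had been seen. The number of arrays and cows was weighed, whereas without intensities the limit set by signal over background is unknown. The fit without the shared cow is counted once. Of 2009 alternative values of 83 single-gene results, 1942 kept their direction and side of the threshold, 35 fell back over it, 10 newly passed and 22 reversed. Where a value changed, the cause was not tested, except that fewer cows or arrays were used where some were left out.

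The count of features that differed between high-Ab and low-Ab cows (0) was unchanged in 22 of 24 alternatives. It was 15 in an array-level fit with the cow as a random block and 1, IL1B, with the shared cow left out. Leaving out each cow gave 0 to 1. Between high-DTH and low-DTH cows the count (0) was unchanged in 23 of 24 and was 2 in the array-level fit, with 0 to 0 on leaving out each cow. For all high against all low cows (0) it was unchanged in 27 of 28, was 9 in the array-level fit, and 0 to 0 on leaving out each cow. The array-level p-values come from arrays, with fitted correlations within a cow of 0.27, 0.12 and 0.17.

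The count of 7 features that differed between the traits was the same in 3 of 27 alternatives and 6 with each array centred on its median. It was 0 with quantile normalization across arrays, only Alexa647, only Alexa555, or the 3 arrays turned or left out. It was also 0 with only arrays 1 and 2, with only arrays 3 to 5, and without the noisiest genes, which removed IL1B and IL1A. It was 4 with a plain mean over arrays, 1 with a median over arrays, 2 with only named genes tested, 18 with every spot tested on its own and 3 in the array-level fit. Leaving out each cow gave 0 to 7, with 7 without high-DTH cow 2, 3 without high-DTH cow 3 and 0 without any other cow. The direction of IL1B and IL1A held in every other alternative, from −2.04 to −0.73 for IL1B (adjusted p from 0.0148 to 0.991) and from −1.75 to −0.57 for IL1A (adjusted p from 0.00101 to 0.991).

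The count of lists that differed between high-Ab and low-Ab cows (1) was the same in 10 of 17 alternatives, but with only arrays 3 to 5 the list called was chemokines (adjusted p = 0.0423) and not T cells (0.0841). It was 0 for camera with an estimated correlation, for the fry rotation test, with the 3 arrays turned and with the 3 arrays left out, 2 with the shared cow left out, chemokines and Th1 (adjusted p = 0.0275 and 0.0368) and not T cells (0.0593), 0 with the shared cow left out and camera with an estimated correlation, and 0 to 2 on leaving out each cow, with 0 without low-Ab cow 1. Between high-DTH and low-DTH cows the count (2) was the same in 7 of 17, but with the 3 arrays left out the lists were chemokines (adjusted p = 0.00346) and MHC class I (0.0166) and not T cells (0.0518). It was 3 with the 3 arrays turned and without low-DTH cow 3, 0 for camera with an estimated correlation, with all cows or with the shared cow left out, and for fry, 4 with only arrays 1 and 2, 1 with only arrays 3 to 5, 4 for camera on ranks, and 1 to 4 on leaving out each cow, with 4 without low-DTH cow 1 and 1 without low-DTH cow 2. Adjusted p ran from 0.000147 to 0.776 for T cell genes and from 0.0275 to 0.891 for chemokine genes in the Ab comparison. In the DTH comparison it ran from 0.000275 to 0.740 for T cell, 0.000474 to 0.740 for chemokine, 0.00632 to 0.880 for MHC class I and 0.0283 to 0.740 for B cell genes.

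The reversed values were all differences that had not passed adjustment. With only arrays 1 and 2, PRP6 (0.049) and IL10RB (−0.075) in the Ab and CD44 (0.036) in the DTH comparison reversed. With only arrays 3 to 5, CD72 (0.069) and BCL2 (−0.070) reversed in the Ab comparison, and CCL3 (−0.18), IL1B (−0.21), LTB (0.065), CCR1 (−0.061), NOD2 (−0.15) and ICAM3 (0.034) in the DTH comparison. With the 3 arrays turned, CD72 in the Ab (0.019) and CD44 in the DTH comparison (0.12) reversed, and with them left out CD72 (0.0022) and CD44 (0.057). CCR3 reversed in the Ab comparison with the shared cow left out (−0.085, range on leaving out each cow −0.085 to 0.41), and CD72 without low-Ab cow 1 (0.0076) or low-Ab cow 3 (0.043, range −0.20 to 0.043). In the DTH comparison CD44 reversed with only Alexa647 (0.18), with a median over arrays (0.071) and without low-DTH cow 3 (0.066, range −0.18 to 0.066), and ICAM3 with only Alexa555 (0.043).

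With the cow number as a replicate block, 0 features passed in limma in the Ab and 0 in the DTH comparison, with 28 at an unadjusted p under 0.05 in each, and the list counts were 1 and 2. High and low cows of the same number had r from −0.515 to −0.126 after removing group means, which gives no sign that the numbers pair the cows.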

Other observations

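Cows chosen for the 2 traits were compared with each other after the split of the cows above had been seen, leaving out the shared cow. Between 5 Ab and 5 DTH cows, limma called 0 of 561 features, with 40 at an unadjusted p under 0.05 against 28.1 by chance, and 0 and 106 with the 3 arrays turned. The smallest p belonged to IL6, a cytokine gene, with ratios higher in Ab than in DTH cows by 0.40 ± 0.08 (adjusted p = 0.483).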
